A study of Mus musculus with 8 samples.

How the data were processed

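Total RNA of mouse peritoneal macrophages was labelled with biotin and hybridised to Illumina Mouse Ref-8 bead arrays, 1 array per sample and 8 arrays in all. The arrays fall into 4 groups of 2: wild-type cells (WT) and cells of a mouse line labelled as lacking the Fc gamma chain (KO), each left unstimulated or given interleukin-4 (IL-4). Groups were taken from the sample titles. The titles number the duplicates but tie no sample to an animal, so every p-value measures only the spread between duplicates, which may be technical. With 2 arrays per group, the number of arrays limits the precision.

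The deposited values are normalized probe intensities on a linear scale. GenomeStudio is named in the submitters' processing notes, without a version or settings. The sorted values of the 8 deposited columns differ by at most 0.57 intensity units, so the table is read here as quantile-normalized between arrays, and its lowest values lie near 78.4 rather than 0, so background had not been subtracted. Both statements come from the values and not from a stated method. A table of non-normalized signals with detection p-values was not used. Its headings match no sample label, and 8 signal columns (16 columns with their detection p-values) were left out for that reason.

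The test fixed before the data were examined was a limma fit on background-corrected, quantile-normalized signals with a detection filter from the detection p-values. Because those signals could not be tied to samples, the fit was made on the deposited normalized intensities. Background was corrected with normexp (saddle-point fit, offset 16) and values were taken to log2, with no further normalization between arrays. In place of the detection p-value, a probe counted as above background on an array when its intensity exceeded the mode of the array's low values plus 1.645 times the standard deviation of the values below that mode. This threshold lay between 93.2 and 93.3 intensity units and called between 54.2% and 54.7% of the probes on each array.

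Of 25697 probes, 23978 carry 1 gene symbol in the platform annotation, 0 carry several and 1719 are unnamed here. Of the named probes, 23962 matched the mouse RefSeq gene table of assembly GRCm38.p6 by Entrez identifier, and 0 symbols changed. That table served only for names and for the order of neighbouring genes, because no genome build is named for the array. Probes above background on both arrays of at least 1 group were kept (14437 probes, of which 13585 have a gene), and each gene was represented by its probe with the highest mean, which left 9859 genes. For 2612 genes this meant a choice among several probes.

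A model of 4 group means was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with a shared variance trend in eBayes (4 residual and 9.32 prior degrees of freedom). The contrasts were the IL-4 response in each genotype, the genotype difference in each condition, their interaction, and the means over both genotypes and over both conditions. Fold changes are on the scale of log2 intensity after background correction and the offset, so for dim genes they depend on both and are not ratios of the deposited intensities. Without the background correction, the IL-4 response of Chil3 in WT, for example, was log2 5.23 instead of 6.46. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Where a gene was not above background on any array of a group, the report gives intensities and no fold for that comparison. Differences between responses that rest on such a group are printed with that limit.

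Gene lists were fixed before the data were examined: 30 lists with 586 entries, of which 28 lists had at least 3 measured members and were tested. Of the entries, 433 were tested, 88 were below background and 65 had no probe named here. Lists were tested with camera at a preset correlation of 0.01, and again with a correlation estimated from the data. With the estimated correlation, 2 of the 35 calls over the 4 comparisons and the interaction remained, both for the IL-4 alternative activation list. The size of the whole response was tested with fry, using the direction of the mean response as gene weights. Figures were drawn with matplotlib 3.10.9.

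Named genes follow a rule fixed before the data were examined: the Fc receptor genes, 12 genes known to respond to IL-4, the 10 largest increases and decreases per contrast among genes past the threshold whose groups did not overlap, and up to 4 members per list. The text prints part of them.

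The fit was tested on simulated data of 9859 genes over 20 rounds, with 200 genes changed in WT with IL-4. Another 200 genes were changed in KO with IL-4, and both sets differ in the interaction. Errors were drawn independently for each gene and array, whereas the real IL-4 response in WT called 1618 genes. The rates below hold for the simulated setting and are not the error rates of these data. For the IL-4 response in WT, 97.5% of changes of 1 log2 unit and 59.3% of changes of 0.58 log2 units were recovered, and 5.16% of the calls were false, when gene variances were drawn from the fitted prior. This setting was chosen after a run with each gene's own shrunken variance had given more false calls than the nominal 5%. With that earlier setting, the false share was 6.75% and recovery was 99.9% and 76.7%. For the interaction, 87.0% of changes of 1 log2 unit and 27.5% of changes of 0.58 log2 units were recovered with variances from the prior. With the other setting these were 95.0% and 41.8%. This recovery was counted on the set changed in KO. The real interaction called 12 genes, fewer than either simulated set. With fewer true differences the adjusted threshold is stricter, so recovery would be lower.

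Alternatives covered the background correction, the offset, the detection filter, the choice of probe, the variance estimate, array weights, the replicate number as a block, fits of 2 groups alone, a fold threshold, the list test and leaving out each array.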

Results

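The data are gene expression profiles of peritoneal macrophages, the resident phagocytes of the mouse abdominal cavity, from C57BL/6 mice. Cells were left to adhere overnight in medium with L929 supernatant, a source of the macrophage growth factor M-CSF, and floating cells were discarded. IL-4, a cytokine of type 2 immunity that drives alternative macrophage activation, was given at 10 ng/ml for 6 h. The comparison asks how macrophages with and without the Fc receptor gamma chain respond to it. Each of the 4 groups had 2 arrays. Duplicates correlated at r = 0.994 to 0.995 across genes, and arrays of different groups at 0.970 to 0.988, genes not being independent replicates. The first principal component held 52.0% of the variance and parted stimulated from unstimulated arrays. The second held 26.7% and parted the genotypes.

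Fcer1g, read here as the gene of the knocked-out gamma chain, which carries the signal of activating Fc receptors, was bright in WT and not above background in KO. Its intensity was 12988 in unstimulated WT and 10043 ± 181 (SD, n = 2) with IL-4. In KO it was 86.6 ± 1.27 unstimulated and 89.2 ± 3.64 with IL-4, under the background threshold on all 4 arrays. The difference passed unstimulated (limma adjusted p = 2.3e-15) and with IL-4 (adjusted p = 5.0e-15). Fcgr3, the low-affinity IgG receptor that pairs with this chain, was higher in KO. The difference was 2.90-fold unstimulated (6473 ± 88.7 against 2279 ± 104) and 3.54-fold with IL-4. Counted in tested genes from Fcer1g, Fcgr3, Fcgr4 and Fcgr2b lie at positions -2, -3 and -4, where genotype differences were dense. Their genotype differences therefore cannot be assigned to the missing chain rather than to this region. Fcgr4 was 2.86-fold higher in KO with IL-4 (adjusted p = 0.0104), and its unstimulated difference of 0.83 ± 0.31 (log2, SE) did not pass (adjusted p = 0.181). It ran from 0.39 without KO_unstim replicate 2 and 0.44 without WT_unstim replicate 1 to 1.26 without KO_unstim replicate 1, and passed only with the replicate number as a block (adjusted p = 0.00107) or as a block within genotype, chosen after seeing the data (adjusted p = 0.00025). The Fcgr4 call with IL-4 ended without WT_IL4 replicate 1 (log2 1.35, adjusted p = 0.0764), without KO_IL4 replicate 2 (1.04, adjusted p = 0.108) and with robust eBayes (adjusted p = 0.271). Fcgr2b, the inhibitory receptor, rose with IL-4 by 2.42-fold in WT and 1.95-fold in KO. Fcgr1 fell with IL-4, 1.76-fold in WT and 1.61-fold in KO, the latter not past the threshold without KO_unstim replicate 2 (adjusted p = 0.0645).

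**Figure D1:**
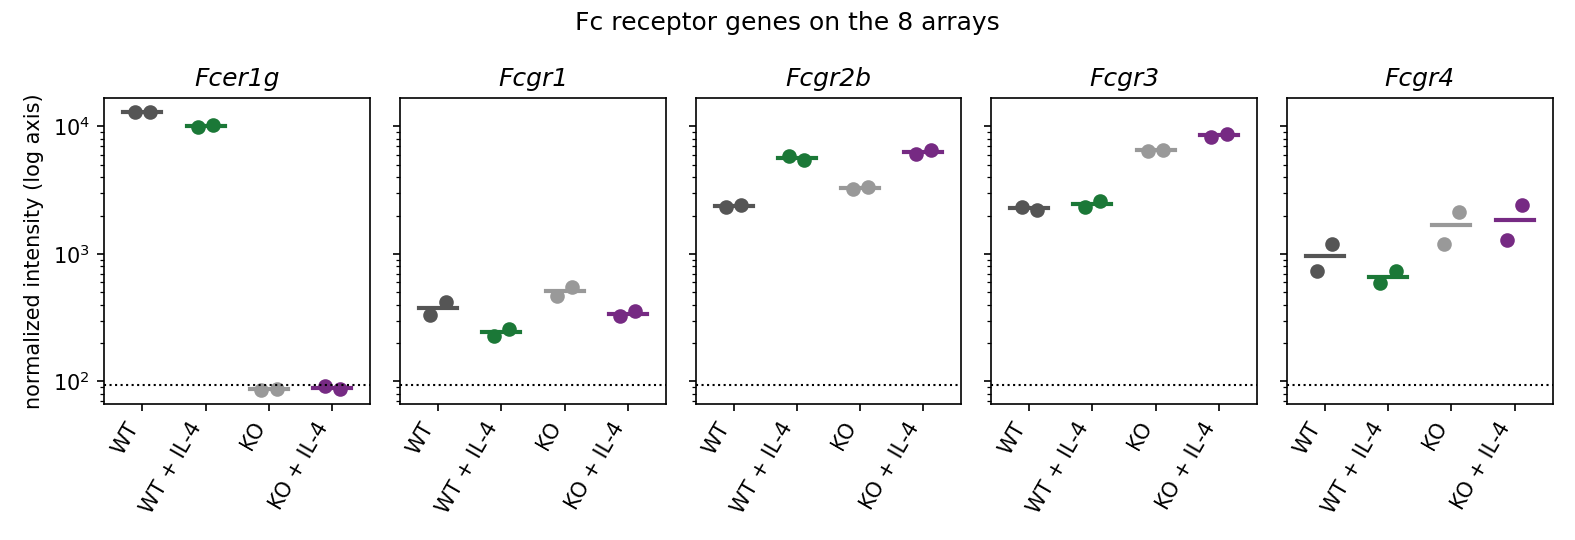
Normalized intensity (log axis) of Fcer1g and 4 Fc gamma receptor genes on each of the 8 arrays, as points, with the group mean as a bar and the mean background threshold as a dotted line. Fcer1g lies at 86.6 and 89.2 in the KO groups, under the threshold, while Fcgr3 is higher in KO than in WT in both conditions.

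The IL-4 response in WT was led by genes of alternative activation. Chil3, a secreted chitinase-like protein, rose 87.8-fold (log2 6.46 ± 0.12 SE, adjusted p = 4.7e-13). Cish, a feedback inhibitor of cytokine signalling, rose 16.9-fold, the mannose receptor Mrc1 13.3-fold, the growth factor Hbegf 12.4-fold and the chemokine Ccl7 11.8-fold. Cdh1, above background on 1 of 2 unstimulated arrays, the arginine transporter Slc7a2, Pparg and Egr2 rose between 5.67- and 7.06-fold. Pparg started near background, with an intensity of 98.7 unstimulated and 288 with IL-4, so its fold depends on the background correction. Ccl24 rose 4.35-fold, Ccl17 4.27-fold, Socs1 2.56-fold, Retnla 1.99-fold and Irf4 1.73-fold, the last not past the threshold without WT_unstim replicate 2 (adjusted p = 0.0561). Pdcd1lg2, not above background before stimulation, rose from an intensity of 90.7 ± 0.0929 to 116 ± 2.04 (adjusted p = 8.3e-05). Arg1, the arginase that marks this state in many settings, had a log2 change of -0.12 ± 0.10 (adjusted p = 0.479). It was already among the brightest genes in unstimulated WT, at 12534 ± 157. Of 28 measured members of the alternative activation list, 24 rose and 0 fell (25 rose adjusted over the list alone), with a median log2 change of 1.28 (camera adjusted p = 2.6e-32, and adjusted p = 0.0123 with an estimated correlation).

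Genes of cholesterol biosynthesis fell with IL-4 in WT. Of 18 measured, 10 fell and 0 rose (11 fell adjusted over the list alone), among them the squalene epoxidase Sqle (4.18-fold), Fdps (3.13-fold) and Hmgcs1 (log2 -1.46 ± 0.12). The list was lower by camera (adjusted p = 7.5e-09), and not with an estimated correlation (adjusted p = 0.457). Of 22 interferon-stimulated genes, 6 fell and 0 rose (8 fell adjusted over the list alone), including Oasl2 (log2 -1.26 ± 0.15) and Rsad2. Camera gave an adjusted p of 0.0026, and the adjusted p was 0.624 with an estimated correlation. Of 17 glycolysis and hypoxia genes 4 fell (4 adjusted over the list alone), with Vegfa at log2 -1.42 ± 0.21. For the list, the camera adjusted p was 0.0397, and the adjusted p was 0.624 with an estimated correlation. Of 19 cell cycle genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0315, and adjusted p = 0.624 with an estimated correlation). Of 4 neutrophil markers 3 fell (3 adjusted over the list alone), with S100a8 at log2 -1.08 ± 0.13. For the list, the camera adjusted p was 0.0240, and the adjusted p was 0.457 with an estimated correlation. Only S100a8 stood well above background in WT with IL-4, at an intensity of 1003. Camp, Elane and Retnlg lay between 91.8 and 97.4, near the background threshold. Outside the lists, the matrix protein Thbs1 fell 8.79-fold, Epb41l3 4.89-fold, Cav1 4.02-fold and the formyl peptide receptor Fpr2 3.84-fold (adjusted p = 0.0885 with robust eBayes). In all, 1618 of 9859 genes passed, 770 higher and 848 lower, and 203 of them changed at least 2-fold. Leaving out WT_unstim replicate 1 gave 1001 genes and leaving out WT_IL4 replicate 2 gave 981. List calls ended for cell cycle without either of these arrays (adjusted p = 0.227 and 0.320), for glycolysis and hypoxia without WT_IL4 replicate 1 and WT_unstim replicate 2 (0.175 and 0.352), and for neutrophil markers without KO_unstim replicate 1 and WT_IL4 replicate 1 (0.102 and 0.456). The interferon call ended without WT_unstim replicate 2 (median -0.02, adjusted p = 0.352), and the median was -0.72 without WT_unstim replicate 1 and -0.18 without WT_IL4 replicate 1. Processing choices ended the neutrophil call (adjusted p = 0.0711 with no background correction) and, with genes above background on all 8 arrays, the glycolysis and cell cycle calls (0.0536 and 0.0610).

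In KO, IL-4 raised the same leading genes. Chil3 rose 115-fold, Slc7a2 16.1-fold, Hbegf 14.5-fold, Mrc1 13.4-fold, Cish 12.5-fold, Ccl7 9.65-fold, the lectin Mgl2 9.48-fold and Egr2 8.83-fold. Retnla, which encodes a secreted resistin-like protein, rose 6.70-fold. Arg1 had a log2 change of 0.06 ± 0.10 (adjusted p = 0.746). Of 28 alternative activation genes, 25 rose and 0 fell (25 adjusted over the list alone; camera adjusted p = 1.4e-30, and adjusted p = 0.0137 with an estimated correlation). Of 18 cholesterol biosynthesis genes, 12 fell and 0 rose (13 fell adjusted over the list alone), including Sqle (5.79-fold), Cyp51 (4.52-fold) and Msmo1 (3.88-fold). Camera gave an adjusted p of 4.8e-11, and the adjusted p was 0.518 with an estimated correlation. Of 18 lysosome genes 4 fell (8 adjusted over the list alone), among them Ctsh (log2 -0.83 ± 0.13) and Hexa (log2 -0.64 ± 0.11), with a camera adjusted p of 0.0060 and an adjusted p of 0.715 with an estimated correlation. Of 19 cell cycle genes 7 rose (9 adjusted over the list alone), led by the replication licensing gene Mcm2 (log2 1.03 ± 0.12). The list had a camera adjusted p of 0.0015, and an adjusted p of 0.715 with an estimated correlation. Of 17 glycolysis and hypoxia genes 8 fell (8 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0229, and adjusted p = 0.715 with an estimated correlation). Among single genes, Thbs1 fell 7.75-fold, the pattern recognition receptor Tlr2 3.98-fold and the prostaglandin synthase Ptges 3.77-fold. In all, 1897 genes passed, 925 higher and 972 lower. Leaving out 1 array gave 1225 (KO_unstim replicate 1), 1231 (KO_unstim replicate 2) and 1121 (KO_IL4 replicate 2).

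**Figure D2:**
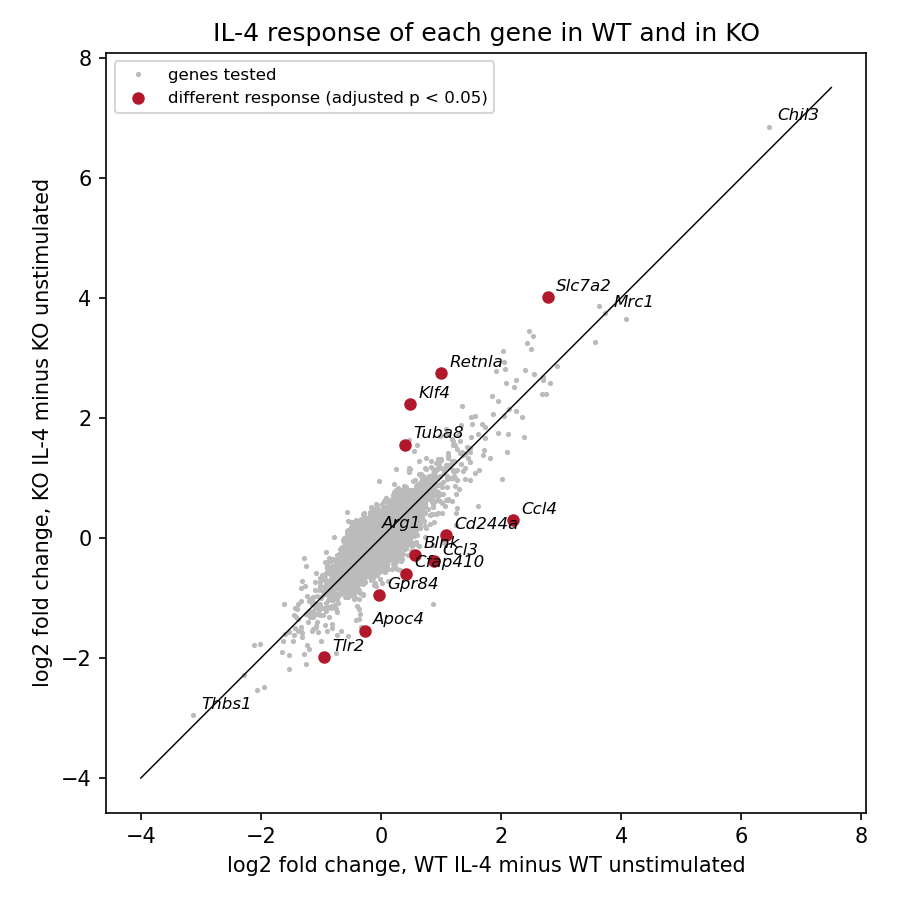
Log2 fold change with IL-4 of each of 9859 genes in WT (x axis) and in KO (y axis), with the line of equal response and the 12 genes whose response differed between genotypes in red. Most responding genes lie near the line, with Chil3 at 6.46 and 6.85.

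The responses of both genotypes were alike across genes (Pearson r = 0.831, Spearman rho = 0.667 over 9859 genes, which are not independent replicates). Both rose for 572 genes, against 72.2 for independent lists, and both fell for 572, against 83.6. Only 1 gene rose in WT and fell in KO, and 2 did the reverse. Over the 2862 genes that passed in the mean response, the signed difference between KO and WT had a median of 0.04 log2 units, larger in KO for 1654 genes and smaller for 1208. It did not pass by the rotation test fry of limma (two-sided p = 0.0504), and an exact permutation of 2 arrays against 2 cannot go below 0.333. The median ranged from 0.0684 and 0.0814, past the threshold of fry, without KO_unstim replicate 1 and without KO_IL4 replicate 1, to 0.0178 without WT_IL4 replicate 1 and -0.0019 without WT_unstim replicate 2, so its sign rests on single arrays.

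A test of the difference between the responses found 12 genes (limma, 647 at an unadjusted p under 0.05). Of these, only Ccl4 and Tlr2 passed under every alternative that measured them. In KO the response was higher for Retnla (log2 1.75 ± 0.27, adjusted p = 0.0327), for Slc7a2 (1.23 ± 0.15, adjusted p = 0.0046), for the transcription factor Klf4 (adjusted p = 0.0327) and for Tuba8 (adjusted p = 0.0390). Unstimulated levels of Klf4 (90.8 in WT, 96.0 in KO) and Tuba8 (92.4 and 87.0) lay at background, with Klf4 above it on 0 and 1 arrays and Tuba8 on 1 and 0. With IL-4 the intensities were 101 in WT and 210 in KO for Klf4, and 101 and 128 for Tuba8. Slc7a2 started lower in unstimulated KO, by 1.18 log2 units. The chemokine Ccl4 rose in WT (log2 2.19 ± 0.13) and had a change of 0.30 ± 0.13 in KO, a difference of -1.89 ± 0.19 (adjusted p = 0.0012). Ccl3 had a difference of -1.26 ± 0.21, and Tlr2, which fell in both genotypes, of -1.04 ± 0.11 (adjusted p = 0.0023). The others with a lower response in KO were Apoc4, above background on both arrays of unstimulated KO alone, Cd244a, Cfap410, Gpr84 and Blnk. Cd244a lay near background in KO (94.4 unstimulated and 95.4 with IL-4). It is at position 11 from Fcer1g, in the region where genotype differences were dense. The interaction count was 5 without KO_unstim replicate 1, 7 without KO_IL4 replicate 1, 4 without KO_IL4 replicate 2, and 3 without each of WT_unstim replicate 2, KO_unstim replicate 2 and WT_IL4 replicate 2.

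**Figure D3:**
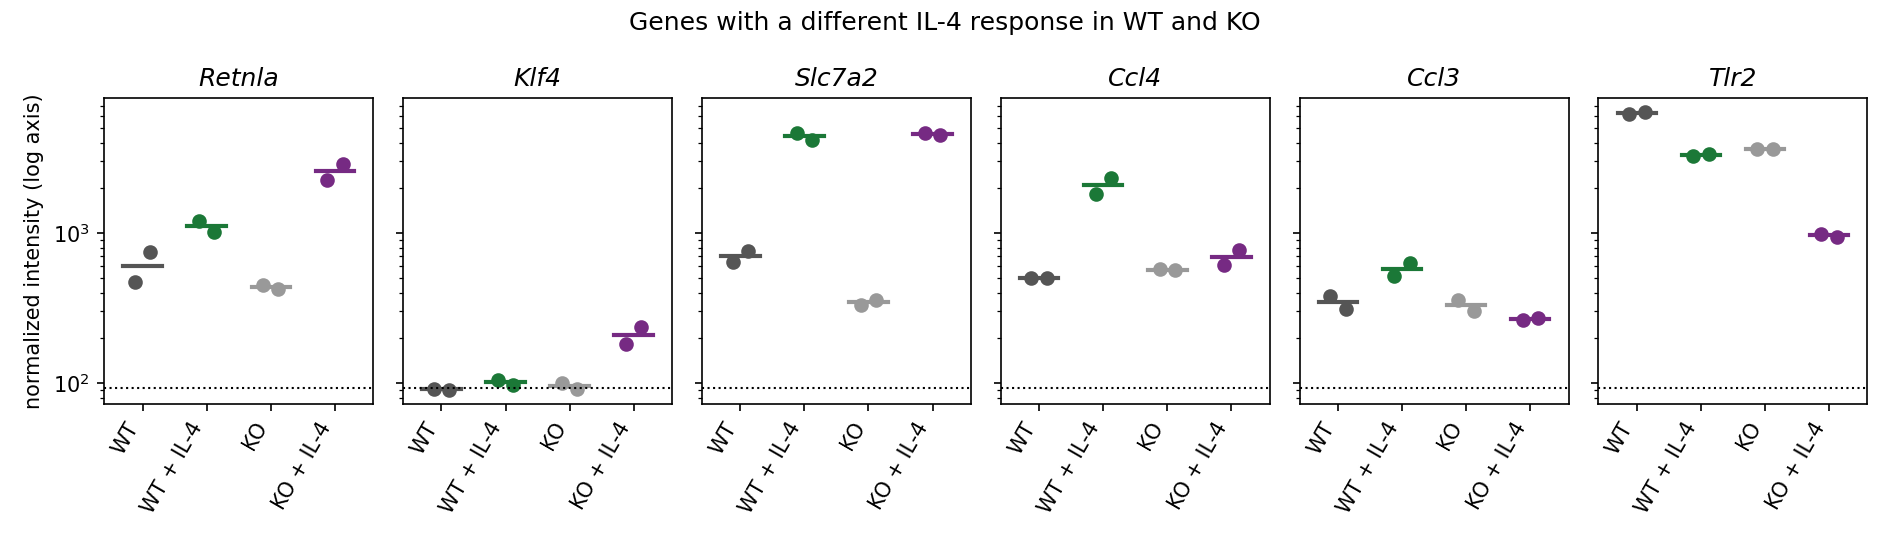
Normalized intensity (log axis) of 6 of the 12 genes whose IL-4 response differed between genotypes, on each of the 8 arrays, as points, with the group mean as a bar and the mean background threshold as a dotted line. Ccl4 averages 2076 in WT with IL-4 and 691 in KO with IL-4.

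Without stimulation, inflammatory genes were lower in KO. Of 22 NF-kB target genes, 10 were lower and 0 higher (12 lower adjusted over the list alone), with Cxcl1, a neutrophil chemoattractant, 4.47-fold lower, Tnf at log2 -1.48 ± 0.13 and the adhesion molecule Icam1 at -1.41 ± 0.09. Camera gave an adjusted p of 9.6e-12, and the adjusted p was 0.183 with an estimated correlation. Of 17 immediate early genes, 5 were lower and 1 higher (8 and 2 adjusted over the list alone). Dusp1 (log2 -0.96 ± 0.12) and Fos (-0.93 ± 0.15) were among the lower ones. The list had a camera adjusted p of 0.0025, and an adjusted p of 0.362 with an estimated correlation. The matrix metalloproteinases Mmp9 and Mmp14 were 5.20- and 4.79-fold lower, Ptges 4.82-fold, Fpr2 5.42-fold and haptoglobin, Hp, 4.08-fold; the last 2 did not pass with robust eBayes (adjusted p = 0.108 and 0.146). Of 17 glycolysis and hypoxia genes 2 were lower (4 adjusted over the list alone; camera adjusted p = 0.0013, and adjusted p = 0.481 with an estimated correlation).

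Genes of resident macrophages and of debris uptake were higher in unstimulated KO. Of 14 markers of large peritoneal macrophages, 6 were higher and 1 lower (9 and 3 adjusted over the list alone), with the complement receptor Vsig4 2.86-fold higher and the lineage factor Gata6 at log2 0.74 ± 0.09 (adjusted p = 2.5e-05, and adjusted p = 0.247 with an estimated correlation). The markers Selp, Tgfb2 and F5 (log2 1.33, 1.16 and 0.48) lie among the 100 tested genes on each side of Fcer1g. Their differences cannot be told from those of this region. The list call held without these neighbours, a setting chosen after seeing the data. Of 17 scavenging, efferocytosis and complement genes, 7 were higher and 2 lower (8 and 2 adjusted over the list alone). Gas6, a bridge to dying cells, was 3.19-fold higher and C1qb was at log2 0.70 ± 0.09. The list had a camera adjusted p of 0.00095, and an adjusted p of 0.183 with an estimated correlation. Of 18 lysosome genes 5 were higher (8 adjusted over the list alone), including Grn and Lamp1. This list had a camera adjusted p of 2.5e-05, and an adjusted p of 0.362 with an estimated correlation. Of 18 cholesterol biosynthesis genes 4 were higher (5 adjusted over the list alone; adjusted p = 4.3e-05, and adjusted p = 0.362 with an estimated correlation). Of 4 neutrophil markers 2 were lower (3 adjusted over the list alone). S100a8 was at log2 -0.60 ± 0.13, and Retnlg, not above background in KO, had an intensity of 89.6 against 117. For these markers as a list, the camera adjusted p was 0.00095, and the adjusted p was 0.183 with an estimated correlation. Of 10 markers of small peritoneal macrophages and dendritic cells 1 was lower, Clec4b1 at log2 -0.99 ± 0.15. Adjusted over the list alone, 1 was lower and 1 higher. The camera adjusted p of the list was 0.0318, and the adjusted p was 0.321 with an estimated correlation. The 10 T and NK cell markers had a median of 0.35 with 0 past the threshold (2 higher adjusted over the list alone; adjusted p = 0.0068, and adjusted p = 0.507 with an estimated correlation). In all, 517 genes passed, 258 higher and 259 lower in KO. The count was 319 without WT_unstim replicate 1, 293 without WT_unstim replicate 2, 327 without KO_unstim replicate 1 and 299 without KO_unstim replicate 2. List calls ended without KO_unstim replicate 1 for neutrophil markers (adjusted p = 0.117) and T and NK cells (0.126), without KO_unstim replicate 2 for cholesterol biosynthesis (0.0513), and without WT_unstim replicate 2 for glycolysis and hypoxia (0.150). The small macrophage and dendritic cell call ended without WT_unstim replicate 1 (0.207), WT_unstim replicate 2 (0.0521), KO_unstim replicate 2 (0.0860) and KO_IL4 replicate 1 (0.0530). It also ended with no background correction (0.0961), offset 50 (0.0650), the mean of a gene's probes (0.0500) and, chosen after seeing the data, without the neighbours of Fcer1g (0.118). The glycolysis call ended with a replicate block within genotype, likewise chosen afterwards (0.149).

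With IL-4, the NF-kB target genes were again lower in KO, 13 of 22 with 0 higher (15 lower adjusted over the list alone). Cxcl1 was 9.50-fold lower, Tnf was at log2 -2.25 ± 0.13 and Icam1 at -1.84 ± 0.09. Il1b had a log2 difference of -2.79 ± 0.35, which was -3.41 without WT_IL4 replicate 1 and -2.16 without WT_IL4 replicate 2 and did not pass with robust eBayes (adjusted p = 0.103). Camera gave an adjusted p of 8.8e-20, and the adjusted p was 0.171 with an estimated correlation. Of 19 chemokine and chemokine receptor genes, 7 were lower and 2 higher (7 and 3 adjusted over the list alone), with Cxcl2 at log2 -2.35 ± 0.18 and Ccl4 at -1.68 ± 0.13 lower, and Ccl2 at 0.90 ± 0.11 higher (camera adjusted p = 0.00058, and adjusted p = 0.180 with an estimated correlation). Ptges was 10.8-fold lower, Mmp14 9.21-fold, Fpr2 7.90-fold (adjusted p = 0.0646 with robust eBayes), Mmp9 6.60-fold and the cystine transporter Slc7a11 6.17-fold. Klf4 was higher (intensity 210 ± 37.2 against 101 ± 5.82). Selp, which lies near Fcer1g on chromosome 1, was 3.86-fold higher, Padi4 2.92-fold and Retnla 2.39-fold. Ccl17 was 2.62-fold lower. Chil3 differed by log2 -0.21 ± 0.12 (adjusted p = 0.422). Of 14 large peritoneal macrophage markers, 7 were higher and 2 lower (7 and 2 adjusted over the list alone; adjusted p = 0.0043, and adjusted p = 0.414 with an estimated correlation). Of 10 T and NK cell markers 3 were higher, Cd3d, Cd3e and Nkg7, of which Cd3d had a log2 difference of 1.20 ± 0.19. Adjusted over the list alone, 5 were higher and 1 lower. The camera adjusted p of the list was 0.0322, and the adjusted p was 0.572 with an estimated correlation. Immediate early genes were again lower, 5 of 17 with 1 higher (6 and 1 adjusted over the list alone; adjusted p = 0.00058, and adjusted p = 0.414 with an estimated correlation). Of 17 scavenging genes 4 were higher and 2 lower (7 and 2 adjusted over the list alone; adjusted p = 0.0322, and adjusted p = 0.414 with an estimated correlation). Glycolysis and hypoxia genes had 3 of 17 lower (3 adjusted over the list alone; adjusted p = 0.00058, and adjusted p = 0.529 with an estimated correlation), and cell cycle genes 3 of 19 higher (3 adjusted over the list alone; adjusted p = 0.0329, and adjusted p = 0.572 with an estimated correlation). In all, 502 genes passed, 240 higher and 262 lower in KO. The count was 261 without WT_IL4 replicate 2 and 278 without KO_IL4 replicate 2. The large macrophage call ended without the neighbours of Fcer1g, a setting chosen after seeing the data (median 0.17, adjusted p = 0.129). Calls ended for T and NK cells without KO_IL4 replicate 1 and WT_IL4 replicate 2 (0.528 and 0.201), for scavenging without KO_IL4 replicate 1, KO_unstim replicate 2 and KO_IL4 replicate 2 (0.0837, 0.0526 and 0.102), and for cell cycle without WT_IL4 replicate 1, KO_IL4 replicate 1 and KO_IL4 replicate 2 (0.304, 0.172 and 0.0686). The T and NK cell call also ended with no background correction (0.0958), offset 50 (0.0535) and no detection filter (0.109), the cell cycle call with the mean of a gene's probes (0.0523), and the scavenging call with the replicate block within genotype (0.0886). Genes higher in KO in both conditions numbered 118, against 6.28 for independent lists, and genes lower in both numbered 169, against 6.88.

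**Figure D4:**
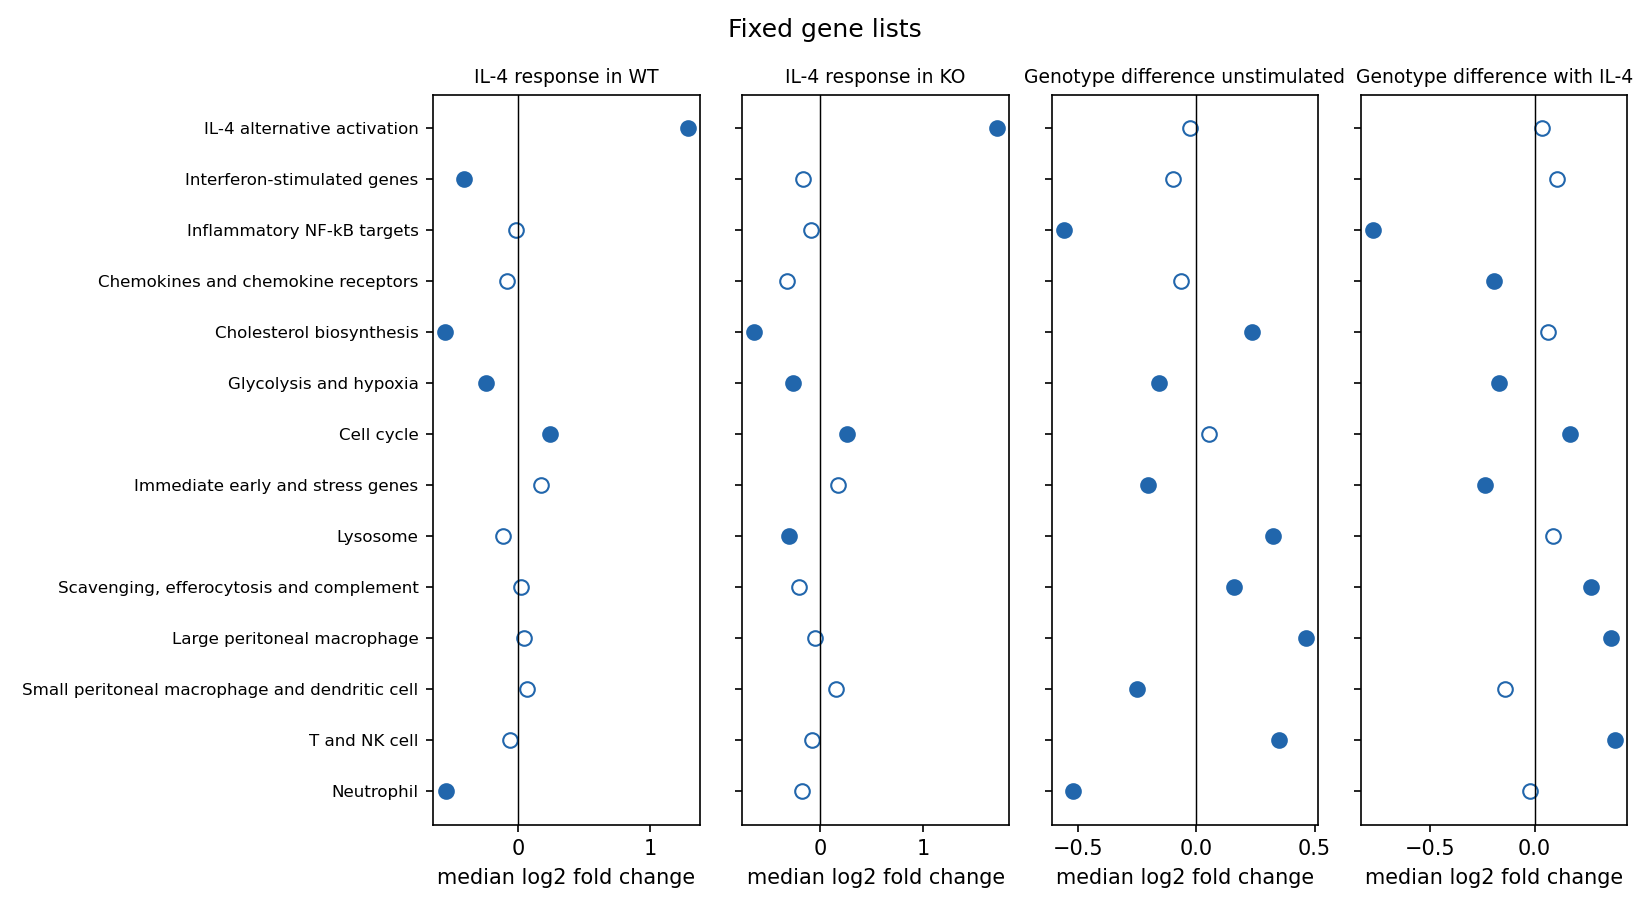
Median log2 fold change (x axis) of each gene list called in at least 1 of 4 comparisons, with filled points for a camera adjusted p under 0.05 at the preset correlation and open points otherwise; the panels differ in x scale. The NF-kB targets lie at -0.56 and -0.78 in the genotype differences, and alternative activation at 1.28 and 1.71 in the IL-4 responses.

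Genes that lie next to Fcer1g on chromosome 1 differed between genotypes in both directions. Of 36 measured neighbours in the list fixed before the data were examined, 9 were higher and 10 lower in KO over both conditions. Adjusted over the list alone, these were 10 and 12. The share that passed over all genes was 10.1%. No common direction was found (camera adjusted p = 0.146), by a test that is not made to detect changes in both directions. Ifi202b, an interferon-inducible DNA sensor gene, was higher in unstimulated KO, with an intensity of 249 ± 35.1 against 91.0 ± 3.54 in WT, where 1 of 2 arrays was above background (adjusted p = 9.5e-07). The nucleotide sugar enzyme gene Uap1 was 7.65-fold lower, and Vsig8, not above background in KO, was lower, with an intensity of 88.6 ± 2.74 against 216 ± 23.1 (adjusted p = 2.1e-07). With IL-4, Ifi202b was higher, with 201 ± 28.6 against 87.4 ± 4.08 in WT, not above background there (adjusted p = 1.4e-06), and Uap1 was 5.84-fold lower. Over both conditions 993 genes passed, 530 higher and 463 lower in KO.

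**Figure D5:**
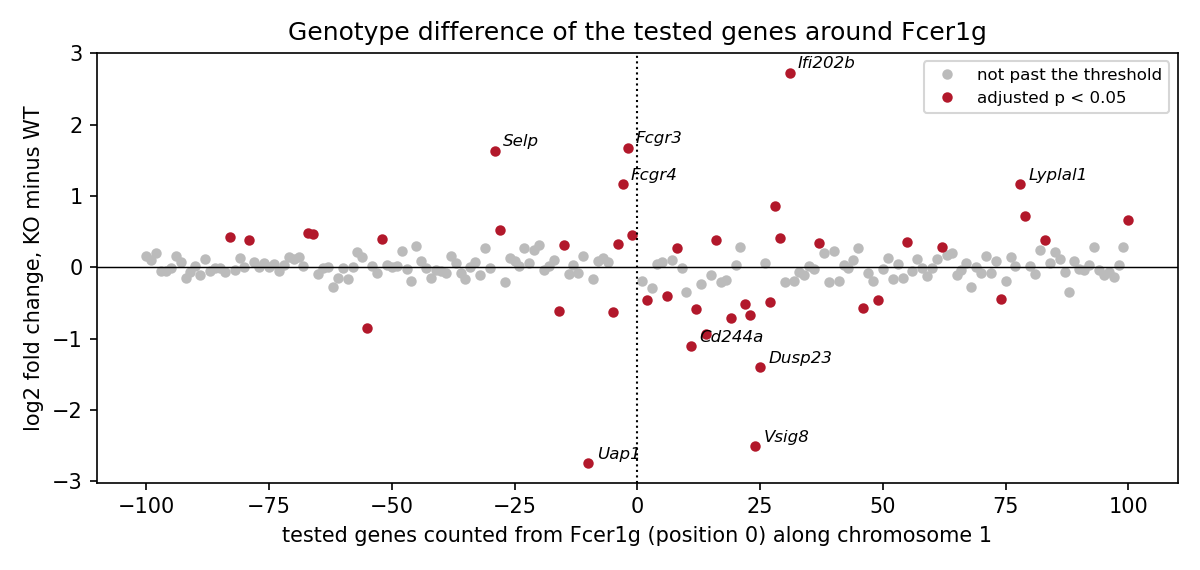
Log2 fold change of KO against WT over both conditions (y axis) for the 100 tested genes on each side of Fcer1g in gene order (x axis), with genes past the threshold in red and Fcer1g itself left out. Of these 200 genes 42 passed, 24 higher and 18 lower.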

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

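The test of the difference between the 2 IL-4 responses was planned, and each result here differed between genotypes by that test. For single genes the values are the log2 response in KO minus that in WT. They were 1.75 for Retnla, 1.74 for Klf4, 1.23 for Slc7a2 and 1.15 for Tuba8. They were -1.89 for Ccl4, -1.28 for Apoc4, -1.26 for Ccl3, -1.04 for Tlr2, -1.04 for Cd244a, -1.02 for Cfap410, -0.93 for Gpr84 and -0.84 for Blnk. Ccl4 and Tlr2 passed under every alternative that measured them. Slc7a2 missed the threshold in 1 alternative and each of the other 9 genes in 5 to 11. The sizes for Klf4, Tuba8 and Apoc4 are uncertain, because they rest on groups not above background and shift with the background correction; over the alternatives they ran from 0.87 to 2.01, from 0.38 to 1.27 and from -1.44 to -0.47. Tuba8 and Klf4 were above background on 1 of the 4 unstimulated arrays each. Apoc4 was above background on both arrays of unstimulated KO and on at most 1 array of any other group. Cd244a was above background on all 8 arrays, but its KO intensities of 94.4 unstimulated and 95.4 with IL-4 lay near the threshold. A second Cd244a probe, above background on 1 array, gave -0.65. Cd244a lies at position 11 from Fcer1g, so its difference cannot be assigned to the missing chain rather than to this region.

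Gene lists also differed between the responses by camera at the preset correlation. The median differences were 0.35 for interferon-stimulated genes, -0.0804 for NF-kB targets, -0.31 for chemokines and their receptors, -0.13 for cholesterol biosynthesis, -0.17 for lysosome genes and 0.41 for neutrophil markers. None of these calls held with an estimated correlation, where the adjusted p lay between 0.228 (chemokines) and 0.642. Over the alternatives the median of the interferon-stimulated genes ran from 0.0415 to 0.548, and that of the NF-kB targets from -0.336 to 0.0421, changing sign without KO_IL4 replicate 1. The interferon call ended without WT_unstim replicate 2 (adjusted p = 0.785). Single omissions also ended the cholesterol, lysosome and neutrophil calls. Of the NF-kB targets 3 passed singly, all with a lower response in KO, and of the interferon-stimulated genes 0 passed.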

How the results depend on the processing

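Counts for the IL-4 responses and the genotype differences stayed within 1.5 times their value under the tested alternatives other than the fold threshold and the omission of single arrays. A block for the replicate number within genotype and the removal of the genes around Fcer1g were chosen after seeing the data. The interaction count of 12 moved to 19 with no background correction, 19 with no detection filter, 4 with probes above background on all 8 arrays and 90 with the replicate block within genotype, for causes not tested. The fry test of the size of the response (main p of 0.0504) came out under the threshold in several settings, where the median difference in log2 units was 0.0268 with no background correction, 0.0338 with offset 50, 0.0417 with no detection filter and 0.0404 without the neighbours of Fcer1g. With array weights, where the median was 0.0398, the p rounds to the threshold itself.

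Requiring at least 2-fold left 203 (IL-4 in WT), 244 (IL-4 in KO), 79 (genotype, unstimulated), 104 (genotype, IL-4), 216 (IL-4 over both genotypes) and 89 (genotype over both conditions), by construction fewer. With an estimated correlation 2 list calls were left of 35. With fry 15 of the 35 stayed past the threshold and 20 did not, while other lists came in, for 37 calls in all. The calls that fry did not keep were interferon, glycolysis and cell cycle for IL-4 in WT, glycolysis and lysosome for IL-4 in KO, cholesterol, glycolysis, immediate early, lysosome and T and NK cell for the unstimulated genotype difference, glycolysis, cell cycle, immediate early and T and NK cell with IL-4, and all 6 of the interaction.

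Leaving out 1 array at a time gave 981 to 1577 genes for IL-4 in WT, 1121 to 1866 for IL-4 in KO, 293 to 526 and 261 to 474 for the genotype difference without and with IL-4, 3 to 10 for the interaction, and a size of -0.0019 to 0.0814. The lone array left in a group was assumed to vary like the other groups.

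Deviations of same-numbered duplicates correlated at 0.153 in WT and 0.232 in KO, and between -0.0933 and 0.0052 across genotypes. There are only 2 such comparisons within a genotype, and the labels give these samples nothing in common beyond a number. With the replicate number as a block the counts were 1712, 1948, 567 and 550 for the 4 comparisons and 14 for the interaction. Of 159 named gene results, 123 kept their call under every alternative run, 28 lost it at least once, 8 gained it at least once and 0 reversed. Of 35 list calls 0 reversed in the direction of the test, though the median of the NF-kB targets in the interaction changed sign in 1 setting.

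Not run were the deposited table in place of the non-normalized one, since it is the main source, and a median shift, which moves nothing in a quantile-normalized table. Fits of 2 groups give no interaction, mean or list value, and the fold threshold gives no list value.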

Other observations

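Tests on the genes around Fcer1g, on neutrophils, on small peritoneal macrophages and dendritic cells, on animals or preparations, and on splits with an IL-4 term were chosen after the result was seen. Single genes of lists without a camera call changed with IL-4 in both genotypes, while other members of these lists moved the opposite way or did not pass. For the antigen presentation, polyamine and Fc receptor lists, the camera adjusted p lay between 0.133 and 0.438. The antigen presentation genes H2-DMa (log2 0.75 ± 0.11 in WT and 0.99 ± 0.11 in KO) and H2-DMb1 (0.50 ± 0.10 and 0.65 ± 0.10) rose, while the co-stimulator Cd86 fell (-0.66 ± 0.11 and -0.87 ± 0.11). The polyamine enzymes Odc1 (0.84 ± 0.09 and 0.68 ± 0.09) and Srm (0.82 ± 0.10 and 0.93 ± 0.10) rose. The C-type lectins Clec4d (-0.91 ± 0.10 and -1.21 ± 0.10) and Clec4n (-1.43 ± 0.19 and -1.49 ± 0.19), listed here among the partners of the gamma chain, fell. The nuclear receptor gene Nr1h3 was lower in KO in both conditions (log2 -0.93 ± 0.11 and -1.43 ± 0.11), and so was the arginine-synthesis gene Ass1 (-1.93 ± 0.17 and -2.08 ± 0.17).

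The IL-4 response over both genotypes gave 2022 genes in a plain fit of 2 groups. Of the 35 splits of the 8 arrays into 4 and 4, only this real one gave as many. The highest other gave 188. The splits exchange single arrays as separate units, but the duplicates may be technical. Such counts therefore cannot exclude a chance difference between preparations. For the genotype difference the planned fit gave 188 genes, and 2 of 35 splits gave as many, itself and the IL-4 split with 2022, so the planned test does not exclude chance. That split calls many more genes because it follows the IL-4 structure of the samples. With IL-4 as a term in the fit, added afterwards, the genotype split gave 954 genes. Of 34 splits 1 gave as many, itself, and the highest other gave 0. This fit also exchanges single arrays and has the same limit.

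Genotype differences were dense around Fcer1g. Among the 50 tested genes on each side, 29 passed over both conditions, more than in any of 7694 other windows of the same length (median 9, highest 23). These windows were moved gene by gene and share most of their genes with the next, so they are not independent. A candidate explanation is a chromosome segment of another strain carried with the knocked-out allele, although the labels give C57BL/6 for both genotypes. The window test was set after this density was seen, so the count of 29 is no evidence for the explanation. A neighbour list fixed before the data were examined shares genes with this window and was also dense in genotype differences. Density does not tell a carried segment from an effect of the missing Fcer1g on its neighbours, so the explanation stays open. The same window also held 41 genes that responded to IL-4, above 99.5% of windows, so part of the density may come from a region rich in responsive genes; the share was 41.0% against 29.1% over all genes, and for genotype 29.0% against 10.1%. An effect of the missing Fcer1g on its neighbours stays open as untested.

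Inflammatory genes were lower in KO, with 15 of 22 NF-kB targets past the threshold over both conditions. Of these, 0 lie among the 100 tested genes on each side of Fcer1g. Map position alone fixes this count, whatever the arrays show. It places the genes outside the region but cannot say whether the region acts on them. Fewer neutrophils could lower such genes, but with IL-4 the 4 markers had a median of -0.0194 and unstimulated a median of -0.52, close to the -0.56 of the NF-kB targets. Only S100a8 stood well above background, so nothing is decided. Fewer small peritoneal macrophages and dendritic cells are possible too: the 10 markers had a median of -0.14 with IL-4 against -0.78 for the NF-kB targets, and of -0.25 unstimulated, but only 2 well-measured markers belong to no other list, Clec4b1 and Napsa. The rule of at least 3 markers well above background and in no other list was set after a version without it had ruled both cell types out. Differences from the inflammatory list with IL-4 were 0.785 ± 0.243 and 0.524 ± 0.0881. They rest only on S100a8 for neutrophils, and on Clec4b1 and Napsa for the small macrophages and dendritic cells. With 4 arrays per genotype and none tied to an animal, the genotype and a difference between animals or preparations cannot be told apart, and the loss of the gamma chain itself stays open.

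The IL-4 response of Arg1 did not pass in either genotype. A ceiling of the normalized signal is a possible explanation. A mean of 13.61 log2 units in unstimulated WT left room above, with 17 genes brighter and the highest at 14.13, which counts against a hard limit at that level but not against compression near the top. Genes past the threshold that rose from below Arg1's unstimulated level to above it in the same genotype numbered 2, where 3 had been set as enough to argue against a ceiling, so the question stays open. Tgm2 did so clearly (12.90 to 13.76 in WT), while Eef1g reached only the KO level of Arg1, 13.51, and stayed below the WT level. No biological explanation was tested.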
